A study of Mus musculus with 2 samples.

How the data were processed

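H3K9me3 ChIP-seq peaks of embryonic mouse heart at day 10.5 were taken from 4 deposited lists, for 1 group of 2 biological replicates. Each replicate was a pool of hearts, from 69 and 51 embryos. The samples were grouped by their labels alone, and no sample was left out. By the deposited file records, each replicate list was derived from the alignment of its library and a control, the pooled list from both libraries and their controls, and the replicated list from the other lists. The aligner, the peak caller and the thresholds of the authors are not given in the sources used here. The replicates' pools held male and female embryos together.

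The deposited lists are in the narrowPeak format on mm10. The deposited score is a display value per peak, and it was not used. The deposited signal value is a ratio, read here as fold enrichment over control on a linear scale, although the files do not name it. The deposited p and q values are −log10 values per peak, the q values adjusted within each list. The lowest −log10 p was 2.00 in replicate 1, 2.02 in replicate 2 and 2.03 in the pooled list. The files give no read counts, so the depth of the libraries is unknown and no counting interval of a signal could be computed. The lists hold only peaks above their threshold, so the absence of a peak gives no upper limit on the mark. Positions are printed counting from 1. Peaks on chromosomes 1 to 19, X and Y were analysed, and the 5 replicated peaks on mitochondrial DNA and the 367 on unplaced contigs are reported apart.

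The annotation was GENCODE M21 on GRCm38.p6, the assembly of mm10, with its soft-masked sequence. The computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, with a random seed of 20. Shuffles placed each peak, with its width, at random on its chromosome outside assembly gaps. Circular shifts moved all peaks of a chromosome by 1 random distance. The main results used 1000 shuffles or shifts, and alternatives of overlap, location and clustering used 200.

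Overlap of the replicates was counted from 1 bp and compared with shuffles of the peaks (one-sided permutation test). Agreement of fold enrichment was described by Spearman's rho over overlapping peaks, with a bootstrap of 200 resamples and no p-value. Density was the number of peaks per Mb outside gaps. The location of a peak was that of its midpoint, in the order promoter (within 1 kb of a transcription start site of any gene type), 5′ UTR, coding exon, 3′ UTR, exon of a non-coding transcript, intron and intergenic. The class of non-coding exons was added to the planned order of classes after the annotation was seen. Its shares were compared with shuffles by a two-sided permutation test.

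For gene lists, a gene counted as marked when a replicated peak touched its body or the 2 kb upstream. Each of 21 lists was compared with 10000 random lists of protein-coding genes from the same deciles of gene length (two-sided permutation test), and p-values were adjusted by the Benjamini-Hochberg method over the 21 lists. Members outside protein-coding genes, such as imprinted non-coding RNAs, were not tested, and Hbb-b1 and Hbb-b2 were not found in the annotation. Neighbouring genes share domains, so circular shifts of the peaks were the check on this test, on the scan of gene families and on the difference between Zfp clusters and other Zfp genes. Zfp clusters were runs of at least 5 Zfp genes with successive starts within 250 kb. The difference between clustered and other Zfp genes was tested by 100000 permutations of the cluster label. First and last exons were compared by a two-sided exact sign test over genes with a peak on 1 of them.

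Domains joined replicated peaks within 10 kb. GC content, the ratio of observed to expected CpG and the share of soft-masked bases were compared with 1 shuffled region per peak, by 100000 sign-flip permutations of the mean difference, or 10000 under alternatives. Primer binding sites were exact matches, on both strands, to sequences complementary to the 3′ ends of 5 tRNAs. Those within 2 kb of a peak were counted against circular shifts (two-sided permutation test), with adjustment over the primers that had sites.

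Genes were named by a rule fixed before the data were examined. It took the 20 protein-coding genes with the most covered bases of gene body, up to 4 members per list with the highest covered share and all members where 3 or fewer had a peak. It also took the 10 peaks of highest fold enrichment, the 5 longest domains, and any cardiac gene of the transcription factor and contractile lists with a peak at its start. Values given with ± are the mean and SD of the 2 replicate lists.

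The alternatives fixed beforehand were each replicate alone, the pooled list, peaks with −log10 q of at least 2, the stronger part of the peaks by fold enrichment, the chromosomes without X and Y, and other overlaps, promoter widths, joining distances, cluster steps, matches, distances and random backgrounds. Replicated peaks that overlap a peak of both replicates by at least 50% of either peak were added as an alternative after the data were examined. The gene list test was checked on simulated lists of 40 genes. At a permutation p under 0.05, not adjusted over lists, it called 1 of 50 lists with no added peaks, 15 with 10 percentage points added, 37 with 20 and 50 with 30. The simulated lists were scattered genes under independently shuffled peaks. These rates therefore do not carry over to adjusted p-values or to gene families in tandem. Lists of 12 to 22 genes and lists with fewer peaks than random were not simulated, so a missing call there leaves a difference open. The overlap, sign-flip and primer site tests were tested on simulated data too. A planted overlap of 24.9% was read as 25.7%. With 40 of 200 sites moved next to peaks the primer site test gave a permutation p = 0.00995, and with 0 moved it gave p = 0.587 by permutation.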

Results

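Trimethylation of histone H3 at lysine 9 (H3K9me3), a mark of heterochromatin, was profiled by ChIP-seq in hearts of B6NCrl mouse embryos at embryonic day 10.5, an early stage of chamber formation. The 2 biological replicates were pools of hearts from 69 embryos (replicate 1) and 51 embryos (replicate 2), male and female together, and formed 1 group without a second condition. The data compared were 4 deposited peak lists on the mm10 assembly. Replicate 1 had 46899 peaks and replicate 2 had 57377. A pooled list, from both libraries, held 75650 peaks, and the replicated list, a selection from the pooled one, held 18495. The depth of the libraries was unknown, since the lists carry no read counts. The chromosomes used, 1 to 19, X and Y, carried 18123 of the replicated peaks. The values called fold enrichment here are the lists' signal values, a column the files do not name.

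The H3K9me3 peaks in the deposited narrow-peak lists were short and weakly enriched, and the strongest of them recurred most often between the replicates. Of the replicate 1 peaks, 28.6% overlapped a replicate 2 peak by at least 1 bp, 30.2 times the mean of 0.946% for shuffled positions. Of the replicate 2 peaks, 24.2% overlapped a replicate 1 peak, 31.1 times the shuffled mean of 0.779%. Both had a one-sided permutation p = 0.000999, the smallest that 1000 shuffles can give. The shares depended on the rule. With at least 50% of the peak covered they were 17.04% and 16.8%, and with at least 50% of both peaks covered 13.7% and 11.2%. For peaks with −log10 q of at least 2 they were 17.9% of 9759 peaks in replicate 1 and 39.4% of 4581 in replicate 2. The shorter list limits the share of the longer, so these shares are not comparable with each other or with those of all peaks. In the top decile by −log10 p, 64.2% of replicate 1 and 58.5% of replicate 2 peaks were found in the other replicate, against 17.1% and 14.3% in the lowest decile. Replicated peaks had a median width of 279 bp and a median fold enrichment of 3.41, and together they covered 6.47 Mb. Those on chromosomes 1 to 19, X and Y covered 6256.68 kb, or 0.236% of these chromosomes outside gaps. Over 13288 overlapping pairs, fold enrichment in the replicates had a Spearman rho of 0.177 across peaks, which are not independent replicates. With peaks of −log10 q of at least 2 the rho was 0.364. The fold values came in steps, as 63.1% of replicated peaks took 1 of the 20 commonest values, so that ranks by fold are coarse.

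**Figure D1:**
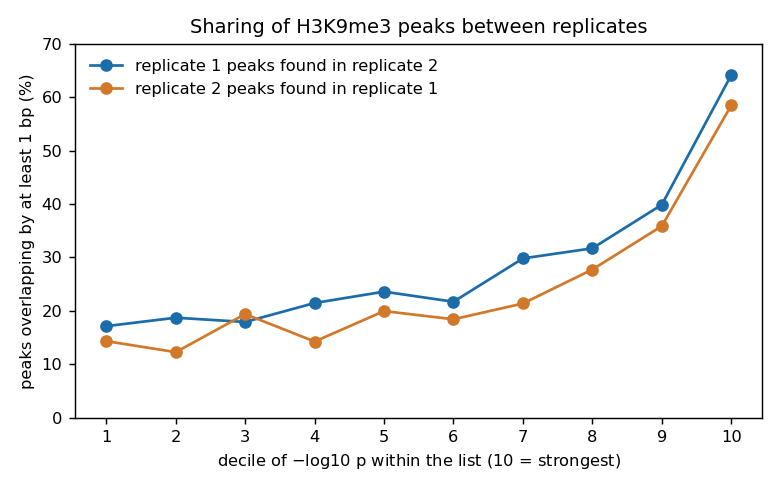
Percentage of the peaks of each replicate that overlap a peak of the other replicate by at least 1 bp, by decile of −log10 p within the list (10 is the strongest). The strongest decile reaches 64.2% in replicate 1 and 58.5% in replicate 2.

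All replicated peaks carried an interval of the pooled list, and 70.3% of them overlapped a peak in each replicate by at least 50% of either peak. Only 38.0% had at least 50% of their own length covered in both replicates. A further 14.4% met the first condition in replicate 1 alone, 13.6% in replicate 2 alone and 1.75% in neither. The 12994 peaks that met it in both replicates served as an alternative set. The replicated set took in 24.4% of the pooled peaks, and it touched 36.7% of the replicate 1 and 30.9% of the replicate 2 peaks.

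Chromosomes 7 and 17, which carry large clusters of zinc finger and receptor genes, held the densest H3K9me3. Chromosome 7 had 3190 replicated peaks, or 22.5 per Mb outside gaps, and chromosome 17 had 1393, or 15.2 per Mb. The median over chromosomes was 5.49 per Mb, so that chromosome 7 stood 4.10 times and chromosome 17 stood 2.77 times above it. Chromosomes 4 and 5 followed at 9.42 and 9.04 peaks per Mb. Chromosome X had 332 replicated peaks at 2.03 per Mb and chromosome Y had 22 at 0.250 per Mb. In the separate replicates chromosome 7 had 49.9 ± 1.47 peaks per Mb (SD, n = 2), whereas X had 4.13 per Mb in replicate 1 and 16.2 per Mb in replicate 2. Relative to the median chromosome, X stood at 0.251 in replicate 1 and at 0.820 in replicate 2, so its low value came mainly from replicate 1. The factor for chromosome 7 was 2.47 in replicate 2 alone. No test of the density was run.

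**Figure D2:**
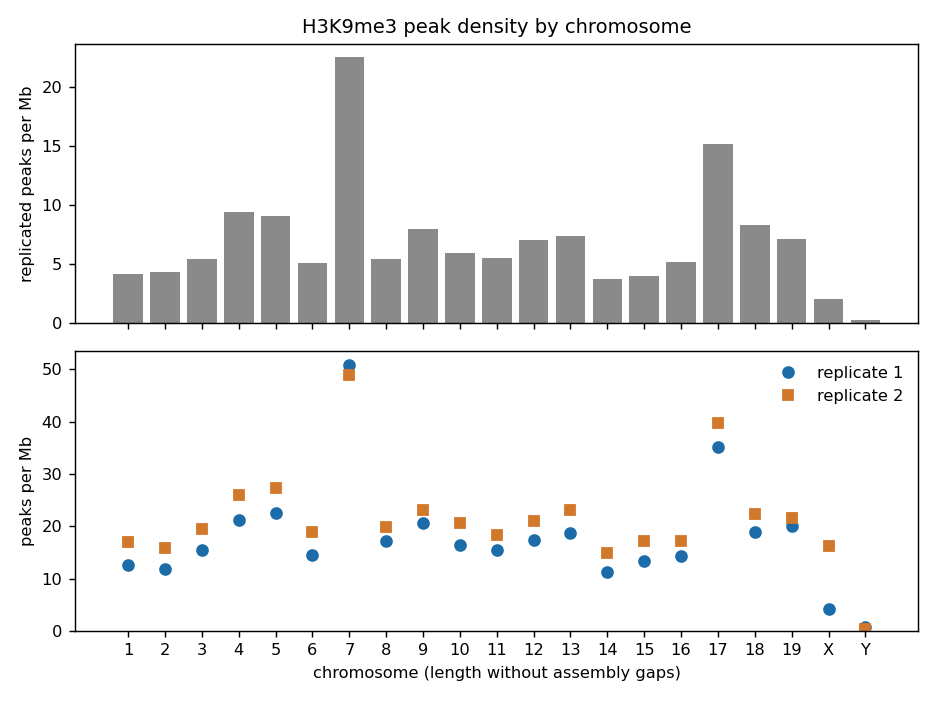
H3K9me3 peaks per Mb of chromosome outside assembly gaps, as bars for the replicated list (top) and as points for each replicate (bottom). Chromosome 7 is the highest in all 3 lists, and chromosome X differs between the replicates, at 4.13 and 16.2 per Mb.

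Relative to genes, H3K9me3 peaks lay over exons, promoters and the space between genes more often than shuffled positions, and in introns less often. Coding exons held 471 peak midpoints (2.60%, against 1.27% of shuffled positions, a ratio of 2.05). Promoters held 1322 (7.29% against 4.84%, ratio 1.51). They were taken within 1 kb of the transcription start sites of all gene types, pseudogenes and non-coding RNAs included. This share is therefore not that of protein-coding genes alone. Exons of non-coding transcripts held 1.16% against 0.673% (ratio 1.73), and intergenic sequence held 60.4% against 51.3% (ratio 1.18). Introns held 26.95% against 40.6% (ratio 0.664). Each of these 5 differences had a two-sided permutation p = 0.002, the smallest that 1000 shuffles can give. The share in 3′ UTRs was 1.52% against 1.29% (permutation p = 0.00599). That excess was lost in replicate 1 alone, at a ratio of 1.03, and turned in replicate 2 alone, at 0.959. With pooled peaks it turned into a deficit past the threshold, at 0.931 (permutation p = 0.0299). Only 10 peaks fell in 5′ UTRs (permutation p = 0.386). Each shuffle placed the peaks independently, although they gather into domains, so these p-values may be too small. Circular shifts were not run for location.

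Of 21 gene lists fixed before the data were examined, 7 carried H3K9me3 more often than random lists of genes of like length. These were the zinc finger (Zfp) genes, the clustered protocadherins, the imprinted genes, the germline genes, the vomeronasal and olfactory receptors and the Cyp2 genes. No list lay below chance at a false discovery rate of 0.05. Across all 21911 protein-coding genes, 2549 (11.6%) had a replicated peak on the gene body or within 2 kb upstream, and 303 (1.38%) had 1 within 1 kb of a transcription start site. In each of the 7 lists the two-sided permutation p was 0.0002, the smallest that 10000 random lists can give, and the adjusted p over 21 lists was 0.0006. When the peaks were shifted along the chromosomes in place of drawing random genes, 5 of the 7 lists were called. The olfactory receptors were not (1.97 points above the shifts, against 2.42 above random lists, permutation, adjusted p = 0.578), nor were the Cyp2 genes (19.96 against 23.8 points, permutation, adjusted p = 0.120), where the excess stayed about as large but the shifts varied more widely than random lists. In replicate 2 alone the germline genes were not called either (permutation, adjusted p = 0.128).

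**Figure D3:**
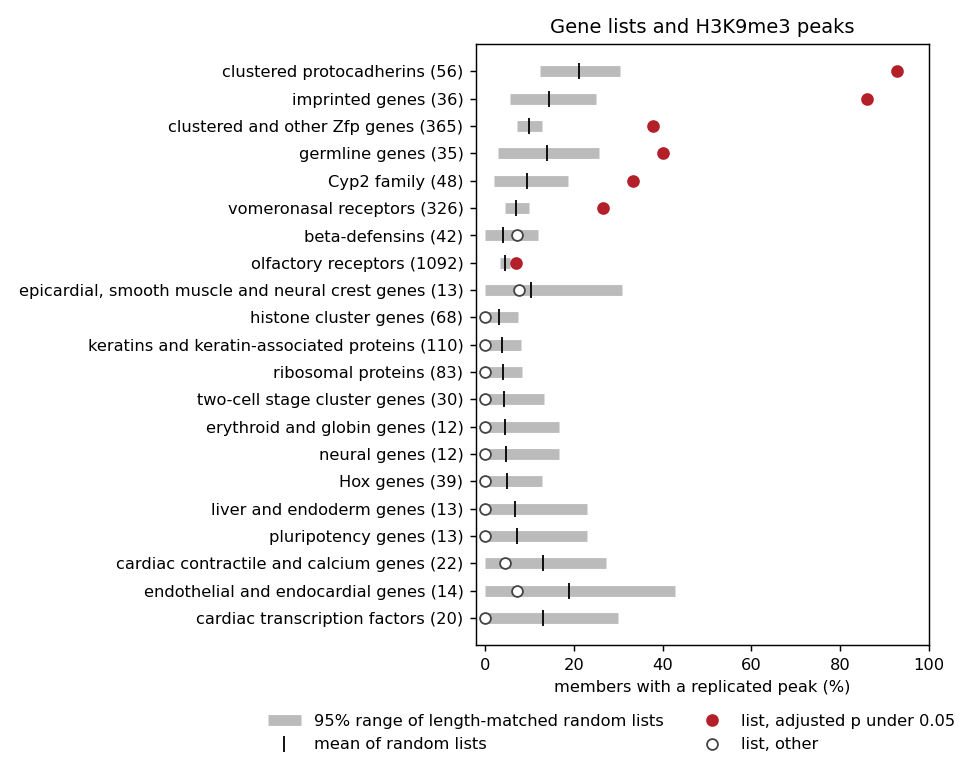
Percentage of the members of each gene list with a replicated H3K9me3 peak on the gene body or within 2 kb upstream (points), with the mean (tick) and 95% range (grey bar) of random gene lists matched on length. The number of members tested is in brackets, and the clustered protocadherins (92.9%) and imprinted genes (86.1%) stand farthest above their random lists.

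Among the Zfp genes, many of which encode DNA-binding repressors, 138 of 365 (37.8%) had a replicated peak, against 9.85% in random lists. The share in the separate replicates was 51.5% ± 0.775 (SD, n = 2), against 23.9% and 24.2% in random lists. Zfp110 (chromosome 7, 12834761 to 12850577) had 63.3% of its gene body and upstream 2 kb covered by 13 replicated peaks, and 46.6% ± 0.746 in the replicates (SD, n = 2). Zfp873 on chromosome 10 (82048123 to 82064745) was covered to 58.1% by 17 peaks, Zfp981 on chromosome 4 (146502027 to 146539395) to 37.1% by 32 peaks, and Zfp90 on chromosome 8 (106415327 to 106426598) to 34.97% by 4 peaks. Their transcription start sites did not stand out, since 6 of the 365 genes had a peak within 1 kb of one (1.64% against 1.13%, permutation, adjusted p = 1).

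Within Zfp genes, H3K9me3 lay on the last exon, which in this family usually encodes the zinc fingers. Of 360 Zfp genes with several exons, 105 had a peak on the last exon and 4 on the first. Among the genes with a peak on only 1 of these exons, it was the last in 103 and the first in 2 (98.1%, 95% Clopper-Pearson interval 93.3 to 99.8%, two-sided exact sign test, p = 2.74e-28). Other protein-coding genes had the last exon alone in 232 and the first alone in 120 (65.9%, exact sign test, p = 2.44e-09). Last exons of Zfp genes were long, with a median of 2498 bp against 150.5 bp for first exons. The sign test takes both exons as equally likely to be hit and the genes as independent. Its p-values therefore allow neither for exon length nor for domains shared by neighbouring genes. Per kb of exon the mean coverage was 131 bases on last and 10.9 on first exons of Zfp genes, against 3.86 and 5.16 in other genes.

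Zfp genes in clusters carried H3K9me3 in 63 of 141 cases (44.7%) and the other Zfp genes in 75 of 224 (33.5%). The difference was 11.2 percentage points (two-sided permutation p = 0.0365), and all 16 clusters held at least 1 gene with a peak. Genes of a cluster share domains, and against circular shifts of the peaks the difference was not called (11.4 points above the shifts, permutation p = 0.0776). The cluster with the most peaks, on chromosome 4 (146971976 to 147848366, Zfp989 to Zfp933), had 138 replicated peaks and a peak on 7 of 10 Zfp genes. The cluster on chromosome 7 from Zfp329 to Zfp446 (12804977 to 12985714), which includes Zfp110, was the densest at 160 peaks per Mb. The cluster with the most marked genes was Zfp84 to Zfp146 on chromosome 7 (29768552 to 30169750), with 47 replicated peaks and a peak on 10 of 15 genes. The difference between clustered and other genes was 18.03 points in replicate 1 alone. It was not past the threshold in replicate 2 alone (10.6 points, permutation p = 0.0539) or with peaks of −log10 q of at least 2 (8.91 points, permutation p = 0.0890). With successive gene starts within 100 kb in place of 250 kb it was 0.0426 points.

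**Figure D4:**
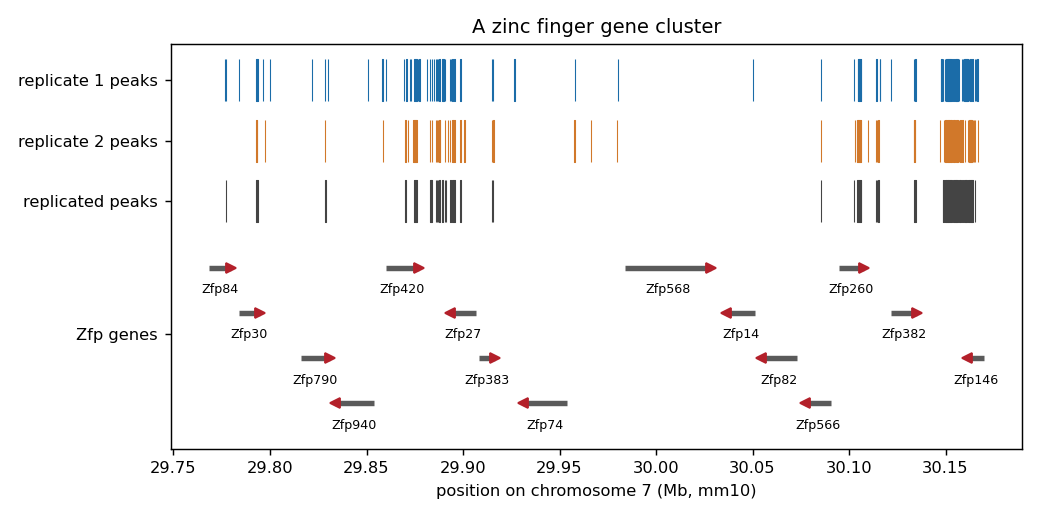
Map of the Zfp84 to Zfp146 cluster on chromosome 7 (mm10), with the peaks of replicate 1 (86), replicate 2 (71) and the replicated list (47) above the Zfp genes, whose arrowheads mark the 3′ end. Replicated peaks gather over the 3′ part of Zfp27 and Zfp146 and in the sequence downstream of each, while Zfp940, Zfp74, Zfp568, Zfp14 and Zfp82 carry none.

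The clustered protocadherins, neuronal adhesion genes that sit in tandem on chromosome 18, were the most completely marked list. A replicated peak lay on 52 of 56 genes (92.9% against 21.2%), and 31 had a peak within 1 kb of the transcription start (55.4% against 1.51%). The share in the separate replicates was 97.3% ± 3.79 (SD, n = 2), against 40.6% and 45.01% in random lists. By bases covered, 15 of the 20 highest-ranked protein-coding genes were Pcdhga1 to Pcdhga9, Pcdhgb1, Pcdhgb2, Pcdhgb4, Pcdhgb5, Pcdha1 and Pcdha2. Pcdhga1 (37661793 to 37841873) led them with 37719 bases of gene body under 74 peaks, 20.9% of its region, and 17.3% ± 3.11 in the replicates (SD, n = 2). These genes share their downstream exons, so the same peaks count for several of them, as they do for Gm42416, Gm37013 and Gm37388, gene models that span the locus and held 97011 to 101509 covered bases. Of the members' own first exons, 51 of 56 had a peak, against a mean of 1.07 in shifted peaks. Pcdhb10 was covered to 37.6% by 4 peaks, Pcdhb22 to 36.5% by 4, Pcdhb15 to 28.5% by 3 and Pcdhb13 to 22.3% by 1. In replicate 2 alone the covered share was 18.6% for Pcdhb10 and 10.7% for Pcdhb15, against 25.4% and 33.6% in replicate 1 alone.

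Imprinted genes, which are expressed from 1 parental allele, carried H3K9me3 in 31 of 36 cases (86.1% against 14.5%), with 91.7% in each replicate, against 31.5% and 33.8% in random lists. A peak lay within 1 kb of a transcription start site in 14 of the 36 (38.9% against 1.56%, permutation, adjusted p = 0.00105). Nnat on chromosome 2 (157560078 to 157562522) was covered to 48.7%, but to 32.3% in replicate 1 and 44.03% in replicate 2. Of the genes of the Prader-Willi region on chromosome 7, Mkrn3 (62417593 to 62420139) was covered to 46.7% and Magel2 (62377010 to 62381640) to 44.97%. In replicate 2 alone these values were lower, at 23.03% for Mkrn3 and 20.5% for Magel2, against 33.3% and 37.1% in replicate 1 alone. Nap1l5 on chromosome 6 (58905233 to 58907076) was covered to 45.3%, but to 9.55% in replicate 1 and 40.1% in replicate 2. The non-coding genes of the list, outside the test, had 8 peaks on Airn, 6 on Meg3, 5 on Kcnq1ot1, 5 on Peg13, 4 on Nespas and 1 on H19, and none on Rian and Mirg.

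Germline genes, which are active in germ cells, had a replicated peak in 14 of 35 cases (40% against 13.95%), and 52.9% ± 6.06 in the replicates (SD, n = 2), against 31.6% and 33.3% in random lists. In replicate 2 alone the excess fell from 26.05 to 15.2 points and was not called (permutation, adjusted p = 0.128). With the peaks seen in both replicates it was 15.1 points (permutation, adjusted p = 0.0414). For 8 of them a peak lay within 1 kb of the transcription start site (22.9% against 1.26%, permutation, adjusted p = 0.00105). The germ cell genes Taf7l on chromosome X (134460118 to 134476490) and Dazl on chromosome 17 (50279395 to 50293636) each had such a peak. Taf7l was covered to 7.84% and Dazl to 4.54%. Mael on chromosome 1 was covered to 1.97%, with a peak at its start, and Meioc on chromosome 11 to 2.93%, without one. In replicate 1 alone the covered share was lower, at 4.41% for Taf7l, 1.91% for Dazl and 0.814% for Mael, and in replicate 2 alone it was 1.55% for Meioc.

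Chemosensory receptor genes of both families were above random lists of genes of like length, although the olfactory excess was not called against shifted peaks (6.96% against 4.99%, permutation, adjusted p = 0.578). Vomeronasal receptors, which detect pheromones, had a peak in 87 of 326 cases (26.7% against 6.96%), and olfactory receptors in 76 of 1092 (6.96% against 4.54%). The shares in the replicates were 39.6% ± 2.60 (against 17.7% and 17.8% in random lists) and 18.5% ± 2.59 (against 12.01% and 12.4%; SD, n = 2). The olfactory excess of 2.42 points was 4.66 in replicate 1 alone and 7.97 in replicate 2 alone. The most covered vomeronasal receptors lay on chromosome 7, namely Vmn1r70 (20.8%), Vmn1r65 (17.96%), Vmn1r66 (17.2%) and Vmn1r179 (16.4%). Among olfactory receptors these were Olfr398 (27.9%), Olfr356 (23.6%), Olfr1349 (18.98%) and Olfr1466 (17.6%). In replicate 2 alone Vmn1r179 was covered to 9.95%, Olfr356 to 13.7% and Olfr1466 to 10.03%. The olfactory excess depended on the length match, since against random lists of any length the difference of the receptors was −4.69 points (permutation, adjusted p = 0.000525). The Cyp2 family of cytochrome P450 enzymes had a peak in 16 of 48 genes (33.3% against 9.50%). In the replicates the share was 56.2% ± 11.8 (SD, n = 2), against 23.9% and 24.7% in random lists, and the excess of 23.8 points became 40.7 in replicate 1 alone. Against shifted peaks, the check for neighbouring genes, the Cyp2 excess was not called (33.3% against 13.4%, permutation, adjusted p = 0.120). Its most covered members were Cyp2d12 (5.89%), Cyp2c29 (5.12%), Cyp2b9 (4.08%, and 6.13% in replicate 1 alone) and Cyp2b13 (3.27%).

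Genes of the heart itself carried few or no replicated H3K9me3 peaks. None of the 20 cardiac transcription factors had one, against 13.1% in random lists (permutation, adjusted p = 0.198), and the share was 5% in replicate 1 and 15% in replicate 2, against 28.8% and 30.3%. In replicate 1 alone the list lay below chance (5% against 28.8%, permutation, adjusted p = 0.0241). Of 22 contractile and calcium handling genes, 1 had a peak (Tpm1, which encodes tropomyosin, covered to 1.32%; 4.55% of the list against 13.04% in random lists, permutation, adjusted p = 0.575), but 27.3% in each separate replicate, against 28.4% and 29.9% in random lists. Of 14 endothelial and endocardial genes, only Tek, the angiopoietin receptor, had a peak (7.14% against 18.9%, permutation, adjusted p = 0.628), and of 13 epicardial, smooth muscle and neural crest genes, only Myh11, the smooth muscle myosin (7.69% against 10.3%, permutation, adjusted p = 1). None of these 4 heart lists was called on the replicated peaks. In the separate replicates the shares were 42.9% and 35.7% for the endothelial list (random lists 39.96% and 43.2%) and 23.1% and 30.8% for the epicardial list (random lists 25.4% and 26.2%). No gene of the cardiac transcription factor or contractile list had a replicated peak within 1 kb of a transcription start site. Random lists had 1.34% and 1.30%, so in lists of this size the absence says little.

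No replicated peak lay on any of 39 Hox, 83 ribosomal protein, 68 histone cluster, 110 keratin and keratin-associated, 30 two-cell stage cluster, 13 pluripotency, 12 erythroid and globin, 12 neural or 13 liver and endoderm genes. Random lists of the same lengths had 3.21 to 7.32%, and none of these differences passed the threshold (permutation, adjusted p from 0.0583 for the keratins to 1). In the replicates the share was 7.69% ± 7.25 for Hox genes (random lists 12.3% and 13.1%) and 19.2% ± 5.44 for pluripotency genes (random lists 16.5% and 17.3%; SD, n = 2). The ribosomal protein genes were below chance in replicate 2 alone (2.41% against 10.3%, permutation, adjusted p = 0.0330) and with pooled peaks (1.205% against 11.8%, permutation, adjusted p = 0.0021), and the histone cluster genes in replicate 1 alone (0% against 7.04%, permutation, adjusted p = 0.0313). Of 42 beta-defensins, Defb33, Defb34 and Defb39 had a peak (7.14% against 4.13%, permutation, adjusted p = 0.707), whereas with pooled peaks 13 had one and the list was above chance (30.95% against 12.5%, permutation, adjusted p = 0.0042).

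H3K9me3 peaks lay closer together than shuffled positions. The median distance to the nearest other replicated peak was 2.79 kb, against 39.96 kb for shuffled positions. Joining peaks within 10 kb gave 9286 domains, 56.7% of the 16381 of shuffled peaks (one-sided permutation p = 0.000999 for both, the smallest that 1000 shuffles can give). H3K9me3 is a broad mark while the lists hold narrow peaks, so 1 broad enriched region may be split into several peaks. Shuffles scatter such pieces, so this test cannot tell split regions from separate regions that lie together. In replicate 1 alone the median distance was 3.27 kb against 16.3 kb, and in replicate 2 alone 3.35 kb against 14.4 kb. Most domains, 6737, held a single peak, while 213 held at least 10 and took in 23.7% of all peaks. The 5 longest domains lay on gene families in tandem. The longest, on chromosome 7 (17594337 to 17829030), spanned 234.7 kb with 125 peaks over Ceacam5 and Ceacam14, cell adhesion genes. The next, also on chromosome 7, covered the secretoglobin genes Scgb2b24 and Scgb1b24 (33563196 to 33747653, 90 peaks) and Vmn1r67 (10307434 to 10480053, 61 peaks). They were followed by Pcdhb1 to Pcdhb8 on chromosome 18 (37228221 to 37386755, 51 peaks) and by the oocyte genes Nlrp4e and Nlrp5 on chromosome 7 (23340602 to 23478366, 58 peaks).

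Among the 20 longest domains, the one with the highest covered share lay on chromosome 1 over Mroh2a, next to Trpm8, the cold-sensing channel. Mroh2a (88226986 to 88262289) had 92.5% of its region covered by 8 peaks, and 89.1% ± 3.98 in the replicates (SD, n = 2). Trpm8 (88277661 to 88389293) was covered to 22.2% by 25 peaks, and 19.5% ± 3.32 in the replicates (SD, n = 2). Mroh2a and the part of Trpm8 up to position 88310877 lie in a domain of 100.6 kb (88210246 to 88310877). This domain also reaches the 3′ end of the Ugt1a glucuronosyltransferase genes and Hjurp, and 73.1% of it was covered. This domain was singled out after its values were seen. The next highest coverage among the 20 was 34.97%. Its peaks were not the strongest, with a highest fold enrichment of 4.61.

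The strongest replicated peak by fold enrichment, at 9.43, lay on the coding exon of Klf14 on chromosome 6 (30957017 to 30958800), an imprinted transcription factor gene. The second, at 9.09, lay at the promoter of Duxf3 on chromosome 10 (58231846 to 58232064), whose product acts at the time of zygotic genome activation. The others of the 10 strongest ranged from 8.74 to 7.96, and in single replicates some were much weaker: 4.49 in replicate 2 for the Sorcs1 peak, 4.74 in replicate 2 for the X peak, 4.90 in replicate 1 for the chromosome 7 peak and 5.21 in replicate 2 for the intergenic chromosome 10 peak. They lay in introns of Il3ra, Sorcs1 and Mvb12b, in the 3′ UTR of Smok2a, at the promoter of an unprocessed pseudogene on chromosome 12 (18135475 to 18136352), and between genes on chromosomes 7, 10 and X.

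By sequence, H3K9me3 peaks were richer in G and C than shuffled regions of the same width and chromosome. The GC content was 48.6% against 42.3%, a mean difference of 6.38 percentage points per peak (SD 9.67, 18123 pairs, two-sided permutation p = 1e-05, the smallest that 100000 resamples can give), and 74.3% of peaks were higher than their pair. The ratio of observed to expected CpG was 0.178 against 0.179 (permutation p = 0.818), and its difference changed direction with the list used. The share of repeat-masked bases was 35.1% against 33.8% (difference 1.30 points, SD 42.9, permutation p = 6e-05), which was not called in either replicate alone (0.0579 points in replicate 2, permutation p = 0.773, and −0.319 points in replicate 1, permutation p = 0.140). Shuffled regions came from all sequence outside gaps. In a like draw, 16.6% of sampled 32-base words occurred more than once in the assembly, against 9.08% in replicated peaks. These comparisons did not allow for where reads can be placed, so they may also reflect where peaks can be called.

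Endogenous retroviruses, located here through the primer binding sites that start their reverse transcription, had H3K9me3 nearby. Sites that match tRNA-Pro lay within 2 kb of a replicated peak in 49 of 174 cases (28.2%), against a mean of 1.85% when the peaks were shifted along the chromosomes. For tRNA-Lys1,2 the count was 22 of 67 (32.8% against 2.44%), for tRNA-Lys3 it was 10 of 62 (16.1% against 2.24%), and for tRNA-Phe it was 130 of 1090 (11.9% against 2.18%). The ratios were 15.2, 13.5, 7.19 and 5.47, each with a two-sided permutation, adjusted p = 0.002, the smallest that 1000 shifts can give. In the separate replicates the shares were 35.1% ± 0.813, 51.5% ± 3.17, 29.8% ± 1.14 and 23.8% ± 1.82 (SD, n = 2). With the more numerous peaks of replicate 2 alone the ratios fell to 5.96, 7.64, 4.40 and 3.76. No site matched tRNA-Leu exactly.

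**Figure D5:**
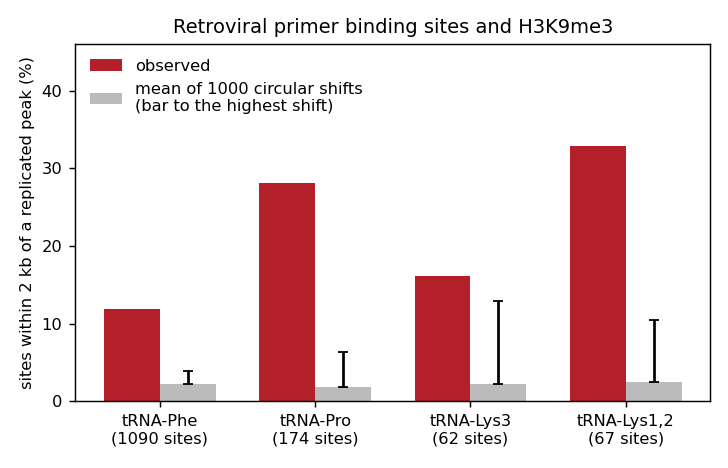
Percentage of exact retroviral primer binding sites within 2 kb of a replicated peak (red), and the mean over 1000 circular shifts of the peaks (grey, with a line to the highest shift). All 4 observed shares, from 11.9% to 32.8%, exceed the highest shift.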

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

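The tests of list length, of strong X peaks and of the Y chromosome, of nested protocadherin models, of words found more than once and of variation within the chromosome 1 domain were chosen only after the results they concern were seen. The use of a bootstrap interval in the test of X fold enrichment was also settled after its value was known.

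Peaks also lay outside the chromosomes compared, in data the comparisons did not use. There were 367 replicated peaks on 23 unplaced contigs, with a median −log10 p of 13.1 and 49 of the 100 replicated peaks of highest −log10 p. Their median fold enrichment was not higher, at 3.22 against 3.41 on chromosomes 1 to 19, X and Y. There were 5 replicated peaks on mitochondrial DNA, which carries no histones, with a median fold enrichment of 1.31.

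The first pattern is the X chromosome, with 675 peaks in replicate 1 and 2654 in replicate 2. The ratio of 3.93 lay far above the 0.959 to 1.36 of the 19 autosomes, which argues against the longer list of replicate 2, and the 10 richest 1 Mb windows held 23.9% of the replicate 2 peaks, which argues against a few regions. A different mix of sexes in sample and control between the replicates remains open, since Y moved the other way, from 62 to 28 peaks (ratio 0.452, bootstrap interval over 31 domains 0.135 to 0.706, below all autosomes), although 1 library per replicate gives no spread between libraries. It would imply a lower dose of X in replicate 1, which the fold enrichment of shared X peaks did not show: the median log2 ratio was −0.0204, inside the autosomes' −0.05 to 0.07, but its bootstrap interval of −0.05 to 0.05 reached below the lowest autosome, so the test does not decide. Extra weak peaks on X in replicate 2 stay open too. In the top decile of each list by −log10 p the ratio on X was 2.71, above the autosomes' 1.22 to 2.06, but 1.93, within their 1.03 to 2.15, without the peaks tied at the bound. The excess fell with strength, as the ratio was 2.63 for −log10 p of at least 5 (autosomes up to 1.22), 1.43 for at least 6 (up to 1.04), 1.18 for at least 7 (up to 1.01) and 1 for at least 8 (up to 1.03). No biological explanation was tested.

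The second pattern is the high share of tandem gene families with a peak, for which reads shared between near-identical copies are a candidate explanation. A comparison of 32-base words inside the peaks with random places of the same genes decides nothing, since all replicated peaks were low in words found more than once in the assembly (9.08%, against 16.6% in shuffled regions). Such words were absent from 6330 of the 18123 peaks, and these peaks alone were set against random lists with the same peaks. The share with such a peak was above all 10000 random lists for the Zfp genes (25.8% against a mean of 6.06%) and the vomeronasal receptors (13.2% against 4.14%). This argues against reads shared between copies in the assembly as the whole cause there, although circular shifts were not run for these peaks. The protocadherins also lay above all random lists (75% against 13.5%). Many of their gene bodies overlap, so the same peaks count for several members, and first exons were not counted with these peaks alone. Shared reads therefore stay open for the protocadherins. For the Cyp2 genes the 14.6% lay above the mean of 5.58% but below the highest random list, 22.9%, so shared reads stay open. Copies missing from the assembly were not tested. Nested gene models are argued against for the protocadherins by 51 members with a peak on their own first exon, above the highest shift of 35, and no biological explanation was tested, as the design has 1 group.

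The third pattern is the domain over Mroh2a and part of Trpm8 on chromosome 1, covered to 73.1%. Reads shared between copies in the assembly are argued against, since without the bases of 32-base words found more than once 70.9% of it was covered, above the 34.97% of the next of the 20 longest domains with all its bases. More copies of the block in the sample than in the control stay open. The coefficient of variation of fold enrichment over its 48 peaks, 0.228 against a median of 0.181 in 212 other domains with at least 10 peaks, does not decide, since extra copies scale the profile that is there. Copies missing from the assembly were not tested, and no biological explanation was tested.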

How the results depend on the processing

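Values of replicated peaks seen in both replicates were added after seeing the data, as were shifted peaks for Zfp clusters (11.4 points, not called) and for the scan of gene families, with which 0 in place of 5 families were called. No paired analysis was possible because the design has 1 group. Of 184 alternative values for 28 comparisons, 152 kept their direction and side of the threshold or stayed within the spread of the replicates. All alternatives run for replicate overlap, the last exon of Zfp genes, GC content, peak clustering and primer binding sites were among these. The reversed sequences matched 0 sites and gave no value. Each replicate alone holds more and weaker peaks than the replicated list, and otherwise the cause was not tested.

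Leaving out each replicate in turn gave 2.47 to 3.10 for chromosome 7 over the median, 2.01 to 2.14 for chromosome 17 and 0.251 to 0.820 for X. It gave 0.959 to 1.03 for 3′ UTRs, 1 to 2 lists below random lists, 10.6 to 18.03 points for Zfp clusters, −0.0142 to −0.00656 for CpG and −0.319 to 0.0579 points for soft-masked bases. Pooled peaks gave 2.76 (chromosome 7), 2.03 (chromosome 17), 0.931 (3′ UTRs), 8 lists above (with the beta-defensins, by 18.4 points), 1 below (the ribosomal proteins, by −10.6) and −0.0140 (CpG). Peaks with −log10 q of at least 2 gave a rho of 0.364, 44.1% of the replicated set covered by 50% in both replicates, 8.91 points for Zfp clusters and 0.00748 for CpG. The stronger peaks by fold enrichment gave 0.0113 for CpG. Peaks seen in both replicates gave 2.89 for chromosome 17 and 0.00766 for CpG. The rho was 0.235 with −log10 p, and 71.5% of the replicated set was covered from 1 bp. Cluster steps within 100 kb gave 0.0426 points. With start sites alone 4 lists were above random lists, and without length matching 5 were below.

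Of 210 gene list differences, 13 changed sign. Leaving out each replicate in turn gave −1.16 to 5.73 points for the pluripotency genes, −2.31 to 4.57 for the epicardial, smooth muscle and neural crest genes, −10.6 to 0.544 for Hox genes, −4.21 to 3.01 for two-cell stage genes and −7.45 to 2.90 for endothelial genes. With pooled peaks the signs that changed were those of the two-cell stage (0.386), pluripotency (3.43) and neural genes (2.44). With the stronger peaks they were the beta-defensins (−0.150) and epicardial genes (1.60). Start sites alone turned the olfactory receptors (−0.0305), and unmatched lists turned them (−4.69) and the beta-defensins (−4.52). Of 270 covered shares of named genes, 117 moved by more than the spread of the replicates. Pooled peaks raised 34 of 54, replicate 2 alone lowered 36 and replicate 1 alone moved 24.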

Other observations

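Other gene families, several of them in tandem, also carried H3K9me3. This scan of 254 families defined by the stem of the gene symbol, with at least 10 members outside the fixed lists, was chosen after the data were examined, as were its repeat with shifted peaks and the comparison of gene biotypes. The families above random genes of like length were 5 in number, and none lay below (permutation, adjusted p = 0.0102 for each). Members of a family share domains, and against 10000 circular shifts of the peaks the excess of these 5 stayed at 22.9 to 53.6 points (26.2 to 61.8 against random genes), with a permutation p from 0.0032 to 0.0318 before adjustment, but none of the 254 families was called (permutation, adjusted p from 0.345 to 0.606 for the 5). The Ceacam adhesion genes had a replicated peak on 10 of 15 members (66.7% against 6.61%), the Skint genes on 9 of 11 (81.8% against 20.0%), and the Nlrp genes, several of them active in oocytes, on 10 of 17 (58.8% against 13.7%). The secretoglobin (Scgb) genes had one on 11 of 34 (32.4% against 3.22%), and Zfp genes whose symbols end in a letter on 11 of 29 (37.9% against 11.7%). In the separate replicates the Ceacam share was 73.3% ± 0, the Skint share 90.9% ± 0, the Nlrp share 73.5% ± 4.16 and the Scgb share 32.4% ± 0 (SD, n = 2).

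Of the other gene biotypes compared, pseudogenes and the V genes of antigen receptors exceeded shifted peaks. Immunoglobulin and T cell receptor V genes had a replicated peak in 13 of 362 cases (3.59%, against 0.429% with shifted peaks, permutation, adjusted p = 0.00799). Unprocessed pseudogenes had one in 168 of 2895 (5.80% against 2.498%) and processed pseudogenes, which arise by retrotransposition, in 249 of 10236 (2.43% against 0.821%), both with a permutation, adjusted p = 0.00599. Long intergenic non-coding RNA genes did not stand out, with 6.87% against 6.72% (permutation, adjusted p = 0.825), nor did snRNA genes (0.362% against 0.332%, permutation, adjusted p = 0.997) or miRNA genes (0.590% against 0.311%, permutation, adjusted p = 0.129).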
